A study of Mus musculus with 30 samples.

How the data were processed

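Spleen cells of 12 female mice were sorted and sequenced, 6 WT B6 and 6 TLR7.1 mice. Per the labels' protocols, each library was made from 500 sorted cells, with full-length cDNA from the SMART-Seq v4 kit and Nextera XT library preparation. The submitters' processing notes name CASAVA 1.8.2, Bowtie, TopHat, Picard, HTSeq 0.4.1, FastQC, SAMtools and the genome build NCBIM37, without a role or an order for each. The annotation release, the strand setting and the read filters are not given in the sources used here. The deposited table holds whole-number read counts per Ensembl gene for each of the 30 libraries, with no normalization. It has 37991 gene identifiers, of which 20439 held any count. Library totals ran from 95002 to 1932427 counts, with a median of 1157458.5. Every column was mapped to its mouse, genotype, population and collection date from the labels, and 0 columns were left unmapped.

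Gene symbols and exon lengths came from the GENCODE M21 annotation, joined by identifier. That release stands on GRCm38 and not on the build of the processing notes, so no coordinates are given, and 32919 identifiers with 99.11% of the counts had a symbol. Read density was checked against exon length. In genes of at least 500 exonic bases the densest gene held 1.48 to 1.59 reads per base in libraries of 1069251 to 1932427 counts. In shallower ones it held 0.562, at 95002 counts, to 1.51, at 908264 counts. The sources used here describe no step that would level the density off.

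Libraries fell into 5 groups of 6, namely WT Mono, WT RPM, TLR7.1 Mono, TLR7.1 RPM and TLR7.1 iHPC. Of the WT mice, 2 were collected on 13 December, 1 on 21 December and 3 on 26 December, and of the TLR7.1 mice 2 on each of these dates. The groups, the comparisons, their tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Genes were kept by edgeR's filterByExpr with the groups given, which left 11030. Counts were scaled by TMM, and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 30 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Tests were two-sided, adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The labels name the mouse, which this model left out and alternatives included. Within-mouse correlations of residual expression, computed from the same data, ran from -0.077 to 0.209 and exceeded 0.1 only in some mice. They do not show that the pairing can be ignored.

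A gene was called apart from both other populations when iHPC were higher than each or lower than each, with the larger of both p values adjusted over all genes. The interaction was the genotype effect in RPM minus that in Mono. Of 33 gene lists, covering pathways, cell identity, other cell types, RNA quality and sex, 32 had tested members and 31 entered the set tests. For each list the members called were counted, adjusted over all genes and again over the list alone. Sets were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry, adjusted over the lists of a comparison. Camera at the preset correlation called 95 of 217 tests of a list in a comparison, 24 of which held with an estimated correlation. Without members that the gates use or another list holds, 76 of the 95 held with the same direction. Fry, which does not compare a list with other genes, called 116.

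The position of iHPC was computed per mouse as the median over genes of the iHPC value minus the Mono value, divided by the RPM value minus the Mono value, on log2 of CPM plus 1. The genes were those called between WT RPM and WT Mono with at least a 4-fold change, and differing at least 2-fold in the same direction in the mouse itself. Positions were tested against 0.5, and correlation differences against 0, by exact two-sided sign-flip tests over the 6 mice. Correlations between sums over lists were tested by exact permutation.

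Named genes are Tlr7 and the genes behind the sort gates, then the 10 largest rises and 10 largest falls of each comparison. The latter needed an adjusted p under 0.05, at least 20 CPM in the higher group, and a symbol that is no predicted gene, clone or pseudogene. Between 2 groups they also needed all 6 libraries of one above all 6 of the other. That was not asked of the interaction or of genes apart from both populations, where 4 of 10 falls and 1 of 10 rises did not meet it against each population. Immunoglobulin and T cell receptor segments were left out there. For each list discussed, 2 to 4 members with the largest changes and the largest change against the direction of the most are named, at the same p and CPM limits. Genes apart from both populations were ranked by the smaller of the log2 changes, and 5 genes per direction are named for the interaction. Of the genes this rule takes, 1 is not reported here.

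Where a group held 0 counts of a gene, the fold is a bound against a floor of 3 counts over its 6 libraries. Where it held 1 to 3 counts, the ratio of pooled counts is given with a 95% interval. These intervals and floors cover counting error only. At these depths simulated changes were recovered in part. Counts were simulated from each gene's mean, a dispersion per gene alike in all groups and the real library sizes. The same test was run on them with 100 genes changed 2-fold and 100 changed 4-fold. It called 30 and 73 of them between iHPC and RPM, with 8 unchanged genes called of 10804 tested. Between iHPC and Mono it called 36 and 75 (4 unchanged, 10812 tested), between RPM and Mono 25 and 69 in TLR7.1 (2 unchanged, 10825 tested) and 26 and 70 in WT mice (3 unchanged, 10818 tested). Between genotypes it called 33 and 77 in Mono (5 unchanged, 10808 tested) and 26 and 60 in RPM (5 unchanged, 10847 tested). For the interaction it called 19 and 55 (6 unchanged, 10825 tested) and for genes apart from both populations 20 and 68 (1 unchanged, 10829 tested). Camera and fry called the changed list and 0 of 20 unchanged ones in 11030 genes. Genes were drawn independently there, so these runs do not show how often sets of correlated genes are called falsely. A simulated position of 0.3, in a fit of 9935 genes, came out at 0.300 over all genes used, 0.239 over genes higher in RPM and 0.327 over genes higher in Mono.

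Alternatives changed 1 choice at a time, except that the mouse as a random effect also changed the test to limma-voom and is to be read against limma-voom without it. They were DESeq2 size factors, no filter on low counts, a filter at 5 CPM in 6 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the mouse as a fixed term in edgeR or as a random effect with limma-voom, and a fit of only the groups compared. Further ones were collection date as a covariate, fits within a date, each mouse left out in turn, counts thinned to the smallest library, which left 4470 genes to test, and an adjusted p under 0.01. For positions and correlations they were other fold limits, pseudocounts of 0.5 and 5 CPM, and Spearman's coefficient. Chosen only after the data had been seen were 5 more. They left out the 3 libraries under 300000 counts, scaled by TMM over genes under 0.05 reads per exonic base, corrected counts for saturation of positions, left out genes over 0.2 reads per base, or kept the library of mouse 24261 as the only iHPC library. Up to 100 other splits of the libraries were run for each count of genes, and all 36 exchanges of 1 WT and 1 TLR7.1 library in RPM. Dixon's test at the 95% level was run on 126 sets of 6 values. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.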

Results

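RNA was sequenced from 30 libraries, each made from 500 cells sorted from the spleen of a female mouse aged 9.4 to 15.7 weeks. The mice were 6 wild-type (WT) B6 and 6 TLR7.1 animals, a line that overexpresses Tlr7, the endosomal receptor for single-stranded RNA. From every mouse came 1 library of Ly6C-high monocytes (Mono) and 1 of red pulp macrophages (RPM), the splenic macrophages that clear aged red blood cells. Each TLR7.1 mouse also gave 1 library of inflammatory hemophagocytes (iHPC), phagocytes that engulf blood cells. That makes 5 groups of n = 6. All sorted cells were live, CD45.2-positive and free of Siglec-F and Ly6G. Mono were sorted as Ly6C+ Ccr2+ CD11b+, RPM as Ly6C- CD31low VCAMhi F4/80+ with no or intermediate CD11b, and iHPC as Ly6C- CD31hi VCAMlow F4/80low CD11b+. Spleens were collected on 13, 21 and 26 December. The total count per library ran from 95002 to 1932427. Group medians were 1584430 in WT Mono, 544757 in WT RPM, 1656511.5 in TLR7.1 Mono, 820242 in TLR7.1 RPM and 1112665 in iHPC. The lowest totals of these groups were 1209266, 95002, 1157446, 268275 and 292507. Values below are normalised CPM, counts scaled to a common library size, given as mean ± SD with n = 6, or log2 fold changes ± SE from edgeR, with 6 libraries in each group. A median of 11811 genes was detected in WT RPM and 13206 in WT Mono. Read density levelled off in abundant genes of the deeper libraries, at no more than 1.59 reads per exonic base, so folds between high levels are compressed.

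Tlr7 and the genes behind the sort gates were read first, since they tell whether the libraries carry the genotype and population of their labels. Tlr7 was 306.8 ± 52.8 CPM in WT Mono and 995 ± 181 in TLR7.1 Mono, a log2 fold change of 1.70 ± 0.218 (adjusted p = 5.94e-06). In RPM it was 222 ± 108 in WT and 1029 ± 340 in TLR7.1 mice, a log2 fold change of 2.18 ± 0.230 (adjusted p = 2.6e-07). iHPC held 1116 ± 133 CPM, and neither difference from the other TLR7.1 populations passed the test (adjusted p = 0.733 against RPM and 0.57 against Mono). Vcam1 was 2486 ± 974 CPM in TLR7.1 RPM, 28.9 ± 16.6 in iHPC and 1.87 ± 2.34 in TLR7.1 Mono. Pecam1, which encodes CD31, was 515.5 ± 78.6 CPM in iHPC, 123 ± 44.9 in TLR7.1 RPM and 13.0 ± 4.81 in TLR7.1 Mono. Itgam, which encodes CD11b, was 187 ± 55.8 CPM in iHPC, 15.5 ± 16.2 in TLR7.1 RPM and 315 ± 26.4 in TLR7.1 Mono. Adgre1, which encodes F4/80, was 428 ± 58.7 CPM in iHPC, 864 ± 193 in TLR7.1 RPM and 383 ± 69.6 in TLR7.1 Mono. Ccr2 was 1528 ± 110 CPM in TLR7.1 Mono, 11.8 ± 9.38 in iHPC and 1.33 ± 1.67 in TLR7.1 RPM. Ly6c2 stood at 500.0 ± 54.8, 10.2 ± 6.46 and 28.6 ± 21.3 CPM in the same order.

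**Figure D1:**
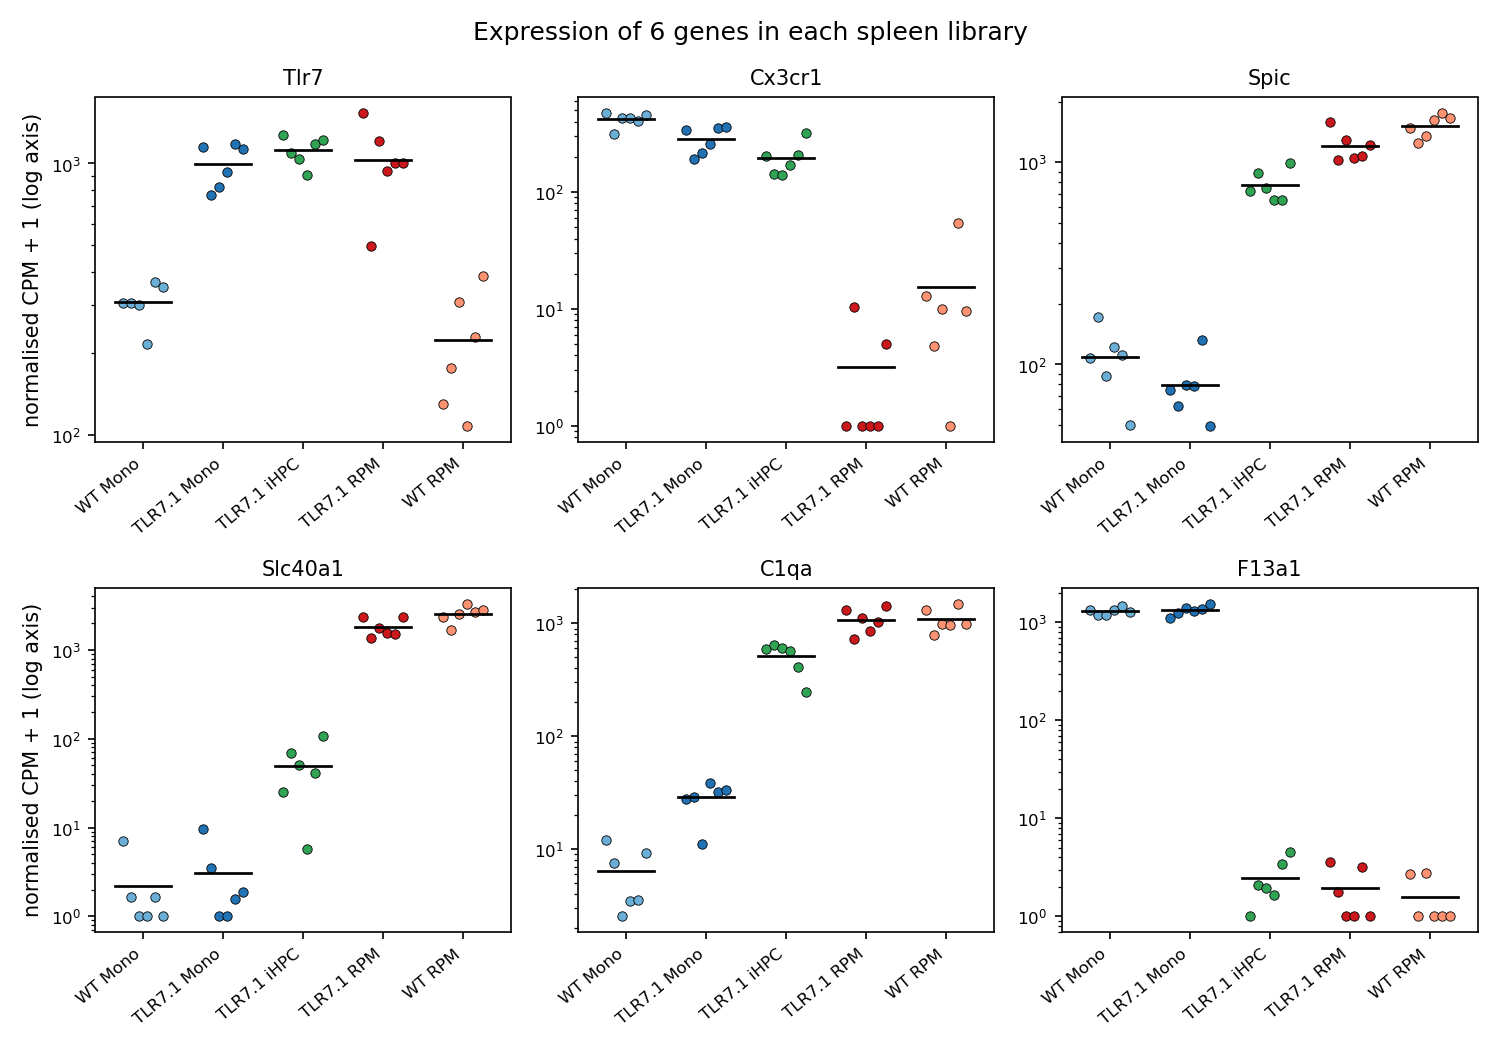
Normalised CPM plus 1 on a log axis for Tlr7, Cx3cr1, Spic, Slc40a1, C1qa and F13a1 in each of the 30 libraries, by group, with a bar at each group mean. Tlr7 averaged 1116 CPM in iHPC, 1029 in TLR7.1 RPM and 222 in WT RPM, and F13a1 averaged 1328 CPM in TLR7.1 Mono against 1.45 in iHPC.

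The comparison of iHPC with RPM asked which genes tell these blood-cell-clearing phagocytes of the same 6 spleens apart. iHPC held most genes of the RPM identity at a lower level: of 25 red pulp macrophage markers, 21 fell, 1 rose and 3 were not called. They held Ly6C-low monocyte markers at a higher level, and complement components and scavenger receptors at a lower one. Inflammatory genes went both ways, 15 of 28 higher and 6 lower. Of 11030 genes tested, 2993 differed at an adjusted p under 0.05, 1499 higher and 1494 lower, and 1073 of the higher and 1028 of the lower ones changed at least 2-fold. Among the red pulp macrophage markers, Slc40a1, which encodes the iron exporter ferroportin, fell from 1812 ± 425 to 48.8 ± 35.2 CPM (log2 -5.38 ± 0.474). The growth factor gene Igf1 (log2 -8.02 ± 0.411) and the mannose receptor gene Mrc1 (log2 -7.98 ± 0.528) fell further. Cd163, the hemoglobin scavenger receptor gene, held 1 count in all iHPC libraries together, 715 times lower by pooled counts (95% counting interval 128 to 28300). Siglec1 held 0 counts in iHPC, at least 54.3-fold lower, with the floor for a group at 0 set at 3 counts over its 6 libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Spic, the transcription factor gene required for RPM, differed less, at 776 ± 138 against 1209 ± 208 CPM (log2 -0.64 ± 0.197, adjusted p = 0.013), and lost its call without mouse 24068 (log2 -0.53). Pparg was the marker that rose (log2 1.15 ± 0.324). The set test (camera) placed the list below other genes (adjusted p = 8.98e-32), and the list alone gave the same counts when adjusted over the list alone, 21 lower and 1 higher.

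Of 23 iron and heme recycling genes, 12 fell and 5 rose in iHPC (14 and 5 adjusted over the list alone). Hmox1, the heme oxygenase gene, fell from 1965 ± 732 to 426 ± 117 CPM (log2 -2.20 ± 0.216) and Lrp1 fell by 2.51 on the log2 scale, while the heme exporter gene Flvcr1 rose (log2 2.40 ± 0.291). Camera gave this list an adjusted p of 0.00163, and adjusted p = 0.0996 with an estimated correlation. Of 29 phagocytosis and scavenger receptor genes, 16 fell and 5 rose (16 and 7 adjusted over the list alone; camera adjusted p = 5.24e-09). Timd4, a phosphatidylserine receptor gene, held 0 counts in iHPC, at least 333-fold lower. Marco (log2 -7.61 ± 0.795) and Stab2 (log2 -7.14 ± 0.537) fell as well, and Pros1 rose (log2 1.47 ± 0.483), a call lost without mouse 24107, 24308 or 24304 (log2 1.17 to 1.28). Complement genes fell in 10 of 14 cases and rose in 2, counts that stayed the same adjusted over the list alone (camera adjusted p = 2.58e-07). C6 went from 588 ± 143 CPM in RPM to 0 counts in iHPC, at least 1100-fold lower. C2 (log2 -5.93 ± 0.835), C4b (log2 -4.86 ± 0.633) and Cd55 (log2 -3.97 ± 0.594) were lower too, and the receptor gene C3ar1 was higher (log2 5.38 ± 0.907).

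Ly6C-low monocyte markers rose in 15 of 24 cases and fell in none (16 adjusted over the list alone; camera adjusted p = 2.7e-09). Cx3cr1, the fractalkine receptor gene, was 196 ± 66.3 CPM in iHPC and 2.22 ± 3.82 in RPM (log2 6.07 ± 0.538). Dusp16 (log2 4.72 ± 0.458), Eno3 (log2 3.45 ± 0.439) and Itgax, which encodes CD11c (log2 3.24 ± 0.284), rose as well. Of 27 chemokine receptor and adhesion genes, 13 rose and 4 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.000303). Ccr1 held 0 counts in RPM, at least 52.9-fold lower than in iHPC, Itga6 was 149 times higher by pooled counts (40.9 to 1230) and Esam rose (log2 4.64 ± 0.773). Cxcr3 was 150 times lower by pooled counts (50.7 to 729). Of 28 inflammatory cytokine and NF-kB target genes, 15 rose and 6 fell (16 and 7 adjusted over the list alone). Il10 was 155 ± 37.4 CPM in iHPC against 12.2 ± 13.3 in RPM (log2 3.98 ± 0.703), and Nfkbiz was 561 ± 120 against 59.6 ± 25.4 (log2 3.20 ± 0.235). Il6 (84.7 ± 49.8 CPM) and Il12b (27.2 ± 11.5 CPM) held 0 counts in RPM, at least 119-fold and 45.8-fold lower. The largest change the other way was that of Il1a (log2 -6.50 ± 0.884). The camera adjusted p of the inflammatory list was 0.0231, and adjusted p = 0.208 with an estimated correlation.

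Markers of other cells moved with this comparison. In iHPC, 10 of 19 erythroid, 12 of 17 B cell and 5 of 9 plasma cell markers were lower (12, 15 and 5 adjusted over the list alone), Klf1 by a log2 of -4.83 ± 0.779 and Jchain by -5.62 ± 1.02. The erythroid markers summed to 2097 ± 874 CPM in iHPC and 4090 ± 698 in RPM. For the erythroid list camera gave an adjusted p = 0.00132, and adjusted p = 0.274 with an estimated correlation; for the B cell list these were 0.000221, and adjusted p = 0.284 with an estimated correlation. Without the library pair of mouse 24304, 7 B cell markers were lower. Basophil and mast cell genes stood out in 5 of the 6 iHPC libraries. Cpa3, a mast cell and basophil protease gene, averaged 408 ± 267 CPM with 0 counts in RPM, at least 610-fold lower. In the iHPC library of mouse 24261, Cpa3, Hdc, Il6, Ier3, Hgf and 14 further genes stood under 10% of the mean of the other 5 libraries. Genes of the dissociation response were higher in 8 of 19 cases and lower in 1, Socs3 by a log2 of 3.26 ± 0.511 (camera adjusted p = 0.00495, and adjusted p = 0.274 with an estimated correlation).

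The 10 genes with the largest rise against RPM among well-expressed genes were Il6, Hdc, Klra17, Ifnlr1, Fut7, Cd276, Ccr1, Tnfsf13b, Il12b and Gria3, each with all 6 iHPC libraries above all 6 RPM libraries. Hdc, the histidine decarboxylase gene, was at least 113-fold higher, Ifnlr1 at least 84.6-fold, Cd276 at least 61.9-fold, Fut7 at least 56.3-fold and Tnfsf13b, which encodes the B cell factor BAFF, at least 44.4-fold. Klra17 was 653 times higher by pooled counts (223 to 3170) and Gria3 373 times (66.6 to 14800). The 10 largest falls were those of C6, Vstm4, Timd4, Scamp5, Col14a1, Fgf1, Cd163, Dysf, Pcolce2 and Ptgis. Vstm4 was at least 342-fold lower, Scamp5 at least 143-fold, Fgf1 at least 98.5-fold, Dysf at least 94.8-fold and Ptgis at least 83.4-fold. Col14a1 was 718 times lower by pooled counts (128 to 28400) and Pcolce2 488 times (135 to 4040). The count of 2993 genes fell to 1753 with only the 12 libraries compared in the fit, to 1145 with counts thinned to the smallest library and to 645 with the library of mouse 24261 as the only iHPC library. In that last setting, chosen after seeing the data, Fgf1 (log2 -8.86), Hdc (4.11), Il12b (7.68), Il10 (3.66), C4b (-4.18), Klf1 (-5.21), Jchain (-9.13), Pparg (1.22), Pros1 (1.71) and Spic (-0.66) were no longer called, and 8 Ly6C-low, 6 inflammatory, 5 iron, 5 complement and 10 phagocytosis genes kept the calls counted above. Of the called genes testable there, 976 of 1498 higher and 977 of 1494 lower ones still changed at least 2-fold in the same direction, so the lost calls do not show that the changes were gone.

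Against Mono of the same mice, iHPC were compared to see which monocyte genes they lacked. Classical monocyte markers were the clearest loss, with 18 of 20 lower, 1 higher and 1 not called (the same counts adjusted over the list alone; camera adjusted p = 1.72e-27). F13a1, the coagulation factor XIII A chain gene, fell from 1328 ± 152 to 1.45 ± 1.3 CPM (log2 -10.04 ± 0.289). Fibronectin gene Fn1 (log2 -7.81 ± 0.318) and Chil3 (log2 -6.63 ± 0.417) fell too, and Vcan held 0 counts in iHPC, at least 421-fold lower. Ms4a6c was the member that rose (log2 0.52 ± 0.186), a call lost without mouse 24308, 24261 or 24380 (log2 0.43 to 0.54). Of 11030 genes, 4270 differed, 2129 higher and 2141 lower, with 1508 and 1562 of them changed at least 2-fold.

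iHPC held more transcript than Mono for 13 of 25 red pulp macrophage markers and less for 4 (14 and 4 adjusted over the list alone). The integrin gene Itgad rose to 341 ± 54.6 CPM (log2 8.62 ± 0.399) and Cd5l, a macrophage survival factor gene, to 347 ± 146 CPM (log2 8.45 ± 0.473). Spic was 776 ± 138 CPM against 78.3 ± 28.0 in Mono (log2 3.30 ± 0.217), Slc40a1 rose by a log2 of 4.32 ± 0.633 and C1qa by 4.20 ± 0.285, while Mrc1 fell (log2 -2.31 ± 0.549). The camera adjusted p of this list was 8.97e-08, and without the members that the gates use or another list holds it was 0.929. Ly6C-low monocyte markers rose in 15 of 24 cases and fell in 3 (16 and 3 adjusted over the list alone; camera adjusted p = 5.22e-07). Cd300e reached 790.2 ± 66.1 CPM (log2 6.32 ± 0.429) and Dusp16 679 ± 47.3 CPM (log2 6.23 ± 0.481). Itgax (log2 5.38 ± 0.312) and Slc12a2 (log2 4.74 ± 0.347) rose, and Ceacam1 fell (log2 -2.97 ± 0.392). Iron and heme recycling genes rose in 11 of 23 cases and fell in 4 (12 and 4 adjusted over the list alone), with ceruloplasmin gene Cp (log2 5.82 ± 0.474) and transferrin receptor gene Tfrc (log2 3.09 ± 0.425) among the former and Lrp1 (log2 -2.02 ± 0.303) among the latter. The camera adjusted p of the iron list was 0.00419, and adjusted p = 0.118 with an estimated correlation.

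Interferon-stimulated genes stood lower in iHPC than in Mono, 30 of 47 type I interferon response genes against 1 higher (31 and 2 adjusted over the list alone). Ifi205 (log2 -6.72 ± 0.930), Slfn5 (log2 -4.55 ± 0.458), Usp18 (log2 -3.69 ± 0.465) and Cxcl10 (log2 -3.42 ± 0.804) fell, and Rsad2, the viperin gene, rose (log2 1.76 ± 0.253). For the interferon list camera gave an adjusted p of 8.97e-08, and adjusted p = 0.118 with an estimated correlation. With the library of mouse 24261 as the only iHPC library, 12 type I interferon genes were called lower. Inflammatory genes went both ways, 8 higher and 11 lower of 28 (9 and 11 adjusted over the list alone). Their median log2 fold change was below 0, at -0.005, while camera ranked the list upward (adjusted p = 0.971). Il10 was 470 times higher by pooled counts (160 to 2280), and chemokine genes Ccl2 (log2 -6.00 ± 0.929) and Ccl9 (log2 -2.87 ± 0.359) fell.

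Most erythroid and megakaryocyte or platelet markers were higher in iHPC than in Mono, while neutrophil markers were lower where they were called. Those higher were 17 of 19 erythroid genes, 7 of 8 megakaryocyte and platelet genes, 7 of 17 B cell genes and all 3 tested eosinophil, basophil and mast cell genes (17, 8, 7 and 3 adjusted over the list alone). Slc4a1, the red cell anion exchanger gene, was 133 times higher by pooled counts (45 to 649), Itga2b 138 times (37.6 to 1150), and the platelet factor gene Pf4 rose by a log2 of 5.91 ± 0.883. Camera gave the erythroid list an adjusted p = 5.63e-06, and adjusted p = 0.118 with an estimated correlation; the B cell list had 0.0103, and adjusted p = 0.496 with an estimated correlation. Neutrophil markers were lower in 5 of 11 cases, 3 without mouse 24308 (camera adjusted p = 0.0345, and adjusted p = 0.47 with an estimated correlation). Dissociation response genes were lower in 10 of 19 cases and higher in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00419, and adjusted p = 0.255 with an estimated correlation). The 10 largest rises were those of Adamdec1, Ptprm, Adam23, Negr1, Ppm1n, Cd200r3, Hs3st2, Itga9, Lox and Fndc1. Adamdec1, a metalloprotease gene, averaged 1389 ± 192 CPM in iHPC and 0.551 ± 1.35 in Mono. Ptprm was at least 512-fold higher, Negr1 at least 451-fold, Ppm1n at least 369-fold, Hs3st2 at least 296-fold and Fndc1 at least 181-fold. By pooled counts Adam23 was 2520 times higher (451 to 99500), Cd200r3 2270 times (407 to 89800), Lox 985 times (176 to 38900) and Itga9 810 times (277 to 3930). Besides Vcan and F13a1 the largest falls were those of Galnt9, Clec5a, Arhgef37, Fcnb, Dmkn, Serpinb8, Prtn3 and Spink2. Arhgef37 was at least 111-fold lower, Fcnb at least 102-fold, Dmkn at least 72.2-fold and Spink2 at least 59.1-fold. By pooled counts Galnt9 was 1300 times lower (234 to 51600), Clec5a 1100 times (197 to 43400), Serpinb8 499 times (89.3 to 19700) and Prtn3 359 times (99.2 to 2970). The count of 4270 genes fell to 1809 in thinned counts and to 1173 with the library of mouse 24261 as the only iHPC library, where Ccl2 (log2 -3.92), Cxcl10 (-4.03), Ifi205 (-5.32), Mrc1 (-1.72) and Ms4a6c (0.42) lost their calls. Of the called genes, 1286 of 2128 higher and 1504 of 2141 lower ones still changed at least 2-fold in the same direction there.

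A further question was which genes set iHPC apart from both other populations at once, and 673 genes did so, 376 higher and 297 lower than in each. Of the Ly6C-low monocyte markers, 8 of 24 were higher than in both and none lower (8 adjusted over the list alone). Dusp16 and Itgax led them, with smaller log2 differences of 4.72 and 3.24, followed by Eno3 at 2.17 and Spn at 2.14. Inflammatory genes were higher in 7 of 28 cases and lower in 3 (8 and 4 adjusted over the list alone). Nfkbiz was 561 ± 120 CPM in iHPC, 116 ± 17.3 in Mono and 59.6 ± 25.4 in RPM, and Ccl2 was lower than in both (log2 -4.11), a call lost without mouse 24107 (log2 -3.25). Il10 and Il6 were higher than in both, Il6 being among the genes under 10% in the library of mouse 24261. Phagocytosis genes were lower in 8 of 29 cases and higher in 3 (the same counts adjusted over the list alone, and 5 lower without mouse 24304). Msr1 (log2 -4.16) and Dock1 (log2 -2.38) were examples, Dock1 being called only without mouse 24068 or 24261 when single mice were left out (log2 -2.54 to -2.35 where it was lost, but -1.52 without 24308 and -1.81 without 24304), and the Fc receptor gene Fcgr4 was higher (log2 0.88). Type I interferon genes were lower in 9 of 47 cases and higher in none (11 adjusted over the list alone), among them Slfn5 (log2 -3.71) and Ifi44 (log2 -3.09), the latter not called without mouse 24308 (log2 -2.43). Among the 10 largest rises were those of Cpa3, Il12b, Cxcl14, Grhl1, Cd200r3, Klra17, Slc5a5, Lox and Abcb1a. Il12b, Cxcl14 and Grhl1 held 0 counts in both other populations and were at least 45.8-fold, 42.2-fold and 37.8-fold above RPM and at least 94.3-fold, 86.8-fold and 77.8-fold above Mono. Klra17, a lectin-like receptor gene, averaged 405 ± 135 CPM in iHPC and 5.43 ± 3.96 in Mono. Cd200r3 was 129 CPM in the library of mouse 24261 and 151 to 334 in the others. The 10 largest falls were those of Tfec, Siglec1, Tmem37, Trim30c, Cd163, Ak8, Fcnb, Flt3, Nr4a2 and Ttc39c. Tfec was 259 times lower than in RPM by pooled counts (71.1 to 2140) and 267 times lower than in Mono (73.8 to 2210). All 18 counts of Ak8 in RPM stood in the library of mouse 24308, and all 20 of Fcnb in that of mouse 24107. For both genes the fall against RPM thus rests on 1 library and was gone without it (log2 0 against RPM, adjusted p = 1), while Ak8 was also not called without mouse 24068 (log2 -5.28). Flt3 (log2 -3.79) and Nr4a2 (log2 -3.0) lost their calls without mouse 24107. The 673 genes became 263 in thinned counts and 62 with the library of mouse 24261 as the only iHPC library, where 3 Ly6C-low and 2 inflammatory genes stayed called. Of those testable there, 371 of 375 higher and 297 of 297 lower genes kept their direction, 252 and 205 of them at 2-fold or more (268 and 219 with all libraries). Of the genes named here that could be tested with that library, Dusp16, Itgax, Nfkbiz, Slfn5, Cd200r3, Klra17, Slc5a5, Lox, Abcb1a and Tfec kept their calls and the others did not. Those that did not had smaller log2 differences of 0.76 for Il6, 0.93 for Fcgr4 and at least 1.58 in size for the rest.

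Where iHPC lie between Mono and RPM was measured over 1845 genes that differed at least 4-fold between WT RPM and WT Mono. On a scale from 0 at the Mono level to 1 at the RPM level of the same mouse, the median gene of iHPC stood at 0.579 ± 0.0949 (n = 6, range 0.446 to 0.663). This did not differ from the midpoint of 0.5 in a two-sided exact sign-flip test (p = 0.125, where 0.031 is the smallest p that 6 mice allow), with 2 of 6 mice under it. RPM-high genes stood at 0.564 ± 0.0808 (exact p = 0.15625) and Mono-high genes at 0.612 ± 0.122 (exact p = 0.09375), and these positions did not differ from each other (difference -0.048, exact p = 0.125). They depended on the settings. With a pseudocount of 5 CPM, Mono-high genes stood at 0.693, past the midpoint (exact p = 0.031), and RPM-high genes at 0.477 on its other side (exact p = 0.5), as they did with an 8-fold limit (0.483, exact p = 0.5). A simulated common position of 0.3 came out at 0.239 over RPM-high and 0.327 over Mono-high genes, a wider gap than the measured one, so the measured gap cannot be read as a difference between these genes. Across genes, which are not independent replicates, the profile of iHPC correlated with Mono of the same mouse at 0.685 ± 0.0556 and with RPM at 0.678 ± 0.0391, a difference of -0.00683 ± 0.0550 (exact p = 0.844). RPM and Mono of the same mouse correlated at 0.563 ± 0.0468.

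RPM were compared with Mono in each genotype as the reference for the comparisons above. Red pulp macrophage markers were higher in RPM in 23 of 25 cases in both genotypes, and classical monocyte markers were lower in 19 of 20 cases in TLR7.1 and 20 of 20 in WT mice (the same counts adjusted over the list alone). In WT mice 5098 genes differed, 2616 higher and 2482 lower, and in TLR7.1 mice 5135, 2640 higher and 2495 lower. Slc40a1 was higher by a log2 of 11.15 ± 0.669 in WT and 9.70 ± 0.616 in TLR7.1 mice, Cd5l by 10.60 ± 0.510 and 10.54 ± 0.479, and Spic by 3.82 ± 0.220 and 3.94 ± 0.222. Camera gave the red pulp macrophage list an adjusted p of 3.11e-43 in WT and 3.26e-38 in TLR7.1 mice. Of 23 iron genes, 15 were higher and 3 lower in both genotypes (15 and 3 in WT, 15 and 4 in TLR7.1 mice adjusted over the list alone), with Tfrc up by a log2 of 3.99 ± 0.497 in WT and 5.0 ± 0.444 in TLR7.1 mice and Bach1 down by -1.95 ± 0.306 and -1.90 ± 0.297. Type I interferon genes were lower in 30 of 47 cases in WT and 27 in TLR7.1 mice, against 4 and 5 higher (31 and 28 lower, 4 and 5 higher adjusted over the list alone). Ms4a4c fell by a log2 of 4.25 and 2.99, and Siglec1 rose most in WT (log2 1.34 ± 0.501) and Rsad2 in TLR7.1 mice (log2 2.18 ± 0.256). The Siglec1 call in WT mice was lost without mouse 24117, 24214, 24415 or 24416 (log2 1.23 to 1.33). The camera adjusted p of the interferon list was 1.6e-05 in WT and 0.00128 in TLR7.1 mice, and adjusted p = 0.177 and 0.284 with an estimated correlation. Erythroid markers were higher in RPM in 17 of 19 cases in WT and 19 of 19 in TLR7.1 mice (19 in each adjusted over the list alone). In WT mice 4 of them stayed called with the mouse as a block, and 4 with only the 12 libraries compared, and the camera adjusted p of 8.34e-05 became adjusted p = 0.168 with an estimated correlation. Plasma cell markers were higher in 5 of 9 cases in WT mice and in 1 without mouse 24117. B cell markers were higher in 9 of 17 cases in WT and 15 in TLR7.1 mice (10 and 17 adjusted over the list alone). In TLR7.1 mice the B cell list had a camera adjusted p of 2.72e-06, and adjusted p = 0.146 with an estimated correlation. Eosinophil, basophil and mast cell markers summed to 1631 ± 379 CPM in WT and 965 ± 161 in TLR7.1 RPM against 5.4 ± 5.1 and 2.3 ± 2.4 in Mono. Nearly all of this was Ccr3, at 1620 ± 372 and 910 ± 207 CPM (log2 9.23 ± 0.471 and 10.22 ± 0.533).

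Lists of RNA quality differed between RPM and Mono as well. Dissociation response genes summed to 2800 ± 600 CPM in WT RPM and 5939 ± 854 in WT Mono, and to 1596 ± 324 and 5718 ± 750 in TLR7.1 mice. Of 19, 10 were lower and 2 higher in WT RPM, and 13 and 1 in TLR7.1 RPM (10 and 3, and 13 and 1, adjusted over the list alone). Socs3 fell by a log2 of 3.40 ± 0.546 in WT and 3.27 ± 0.508 in TLR7.1 mice and Atf3 by 2.63 ± 0.256 and 3.62 ± 0.272, while Hsp90aa1 rose by 1.16 ± 0.218 and 1.12 ± 0.213. Camera gave adjusted p = 0.00826 and 4.95e-06, and adjusted p = 0.242 and 0.0574 with an estimated correlation. Mitochondrial transcripts were higher in RPM in 7 of 7 cases in both genotypes (the same adjusted over the list alone), with sums of 8562 ± 2864 and 7272 ± 2331 CPM against 3056 ± 343 and 3091 ± 321 in Mono. For these camera gave adjusted p = 5.36e-05 in WT and 0.000528 in TLR7.1 mice, and adjusted p = 0.199 and 0.254 with an estimated correlation. The cause of these differences was not tested.

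Among the largest differences in TLR7.1 mice, C6 was at least 1660-fold higher in RPM, Gfra2 at least 652-fold, Slc1a3 at least 576-fold, Slco2b1 at least 553-fold, Marco at least 544-fold and Sema6d at least 542-fold. Ccdc148, Pcolce2 and Hs3st2 were at least 507-fold, 490-fold and 476-fold higher. On the Mono side, Ccr2 was 2300 times lower in RPM by pooled counts (788 to 11200), Mmp8 1960 times (351 to 77300) and Fn1 1420 times (484 to 6860), and F13a1 fell (log2 -10.37). Cysltr1, Ccr1, Clec5a, Ugt1a7c, Adora2b and Trem2 held 0 counts in RPM and were at least 276-fold, 276-fold, 268-fold, 240-fold, 204-fold and 193-fold lower. In WT mice, Epb41l3 was at least 1280-fold higher in RPM, Slc1a3 at least 1060-fold, Gfra2 at least 907-fold, Col14a1 at least 803-fold and Slc45a3 at least 801-fold. Timd4, Ptgis and Plpp3 were at least 661-fold, 568-fold and 530-fold higher, and Itgad was 3140 times higher by pooled counts (869 to 26000). Cd177, Stxbp6, Galnt9, Gapt, Nhsl2 and Rasgrp4 were at least 463-fold, 272-fold, 270-fold, 250-fold, 232-fold and 226-fold lower. Ltb4r1, Slc2a6 and Trem2 were at least 204-fold, 171-fold and 170-fold lower, and F13a1 was 2330 times lower by pooled counts (646 to 19300). Thinned counts gave 2265 genes in WT and 2157 in TLR7.1 mice. They also moved the median log2 fold change of all genes, by 0.159 and 0.107.

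Mono of TLR7.1 and WT mice were compared for the effect of Tlr7 overexpression in monocytes. Of 35 cell cycle genes, 25 were higher in TLR7.1 Mono, none was lower and 10 were not called (32 higher adjusted over the list alone; camera adjusted p = 1.31e-91). Their sum was 4645 ± 1065 CPM in TLR7.1 and 767 ± 329 CPM in WT Mono. The mitotic kinase gene Bub1 rose from 2.97 ± 3.48 to 80.7 ± 25.1 CPM (log2 4.64 ± 0.879), Nusap1 from 13.9 ± 15.0 to 230.1 ± 46.1 (log2 4.05 ± 0.468) and the proliferation marker gene Mki67 from 49.3 ± 19.4 to 313 ± 84.8 (log2 2.66 ± 0.327). Kif11 (log2 4.09 ± 0.512) and Tpx2 (log2 3.66 ± 0.593) rose as well. Neutrophil granule markers moved with them: 8 of 11 were higher and none lower (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.65e-12). Ngp averaged 161 ± 239 CPM, Camp 50.3 ± 89.6 and Wfdc21 35.2 ± 22.1 in TLR7.1 Mono against 0 counts in WT Mono, at least 455-fold, 151-fold and 106-fold higher. The Ngp call was lost without mouse 24028, 24117, 24323, 24214, 24415, 24380 or 24416 (fitted log2 10.03 to 10.48, a size that depends on the prior count), that of Camp without mouse 24117 (fitted log2 8.73), and limma-voom called neither. S100a9 rose by a log2 of 7.28 ± 1.57, a call that limma-voom did not make. Of 14 complement genes, 5 rose and none fell (5 adjusted over the list alone; camera adjusted p = 4.3e-07). C1qa rose from 5.41 ± 3.82 to 27.9 ± 9.39 CPM (log2 2.38 ± 0.346) and C1qc by a log2 of 1.86 ± 0.319. Without mouse 24214, 24261 or 24416, 3 complement genes rose in each case, and without shared members the camera adjusted p was 0.0959.

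In all, 232 genes differed between the genotypes in Mono, 199 higher and 33 lower, and 186 of the higher and 22 of the lower ones changed at least 2-fold. The largest rises were those of Wfdc21, S100a9, Spag5 (log2 5.86 ± 0.908), S100a8 (log2 5.47 ± 1.09), Lrg1 (log2 5.45 ± 0.777), Elane (log2 5.36 ± 0.994), Lcn2 (log2 4.94 ± 0.791), Oip5 (log2 4.65 ± 0.892), Bub1 and Ankle1 (log2 4.41 ± 0.915). Among genes of at least 20 CPM in WT Mono and with all 6 TLR7.1 libraries below all 6 WT libraries, the largest falls ran from Acss1 (log2 -1.56 ± 0.283) and Hpgd, the prostaglandin-degrading enzyme gene (log2 -1.46 ± 0.284), through Dusp6 (log2 -1.19 ± 0.244) and Slc46a3 (log2 -1.18 ± 0.221), to Zbtb20, Cd177, Tgfbr1, Txnip, Ogt and Slc11a1 between -1.10 and -0.68. Zbtb20 kept its call only without mouse 24117, 24323, 24308 or 24380, Cd177 only without 24117, 24308, 24214, 24380 or 24304, and Tgfbr1 only without 24214 or 24304, with log2 values of -1.13 to -0.66 where the calls were lost. Ogt lost its call without mouse 24415 (log2 -0.64) and Adgre4 without 24107, 24261 or 24415 (log2 -0.66 to -0.57). Of 24 Ly6C-low monocyte markers, 2 fell, Hes1 (log2 -1.35 ± 0.262) and Adgre4 (log2 -0.67 ± 0.167), and 6 adjusted over the list alone (camera adjusted p = 2.33e-05, and adjusted p = 0.101 with an estimated correlation). Of 47 type I interferon response genes edgeR called 0 in Mono, and so did DESeq2 and limma-voom, with 1 at an unadjusted p under 0.05. Of 28 inflammatory genes these tools also called 0, with 4 at an unadjusted p under 0.05. Within collection dates, the median log2 fold change of the cell cycle list was 2.96 on 13 December, 1.79 on 21 December with 1 WT library, and 3.12 on 26 December, from group means plus 0.5 CPM. For the neutrophil list these medians were 3.08, 1.33 and 6.62. Within 13 December, with 2 mice per genotype, edgeR called 0 genes and 329 had an unadjusted p under 0.05. Within 26 December 105 genes were called, and thinned counts gave 50. The fit with only the 12 Mono libraries called 737 genes, limma-voom 405.

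**Figure D2:**
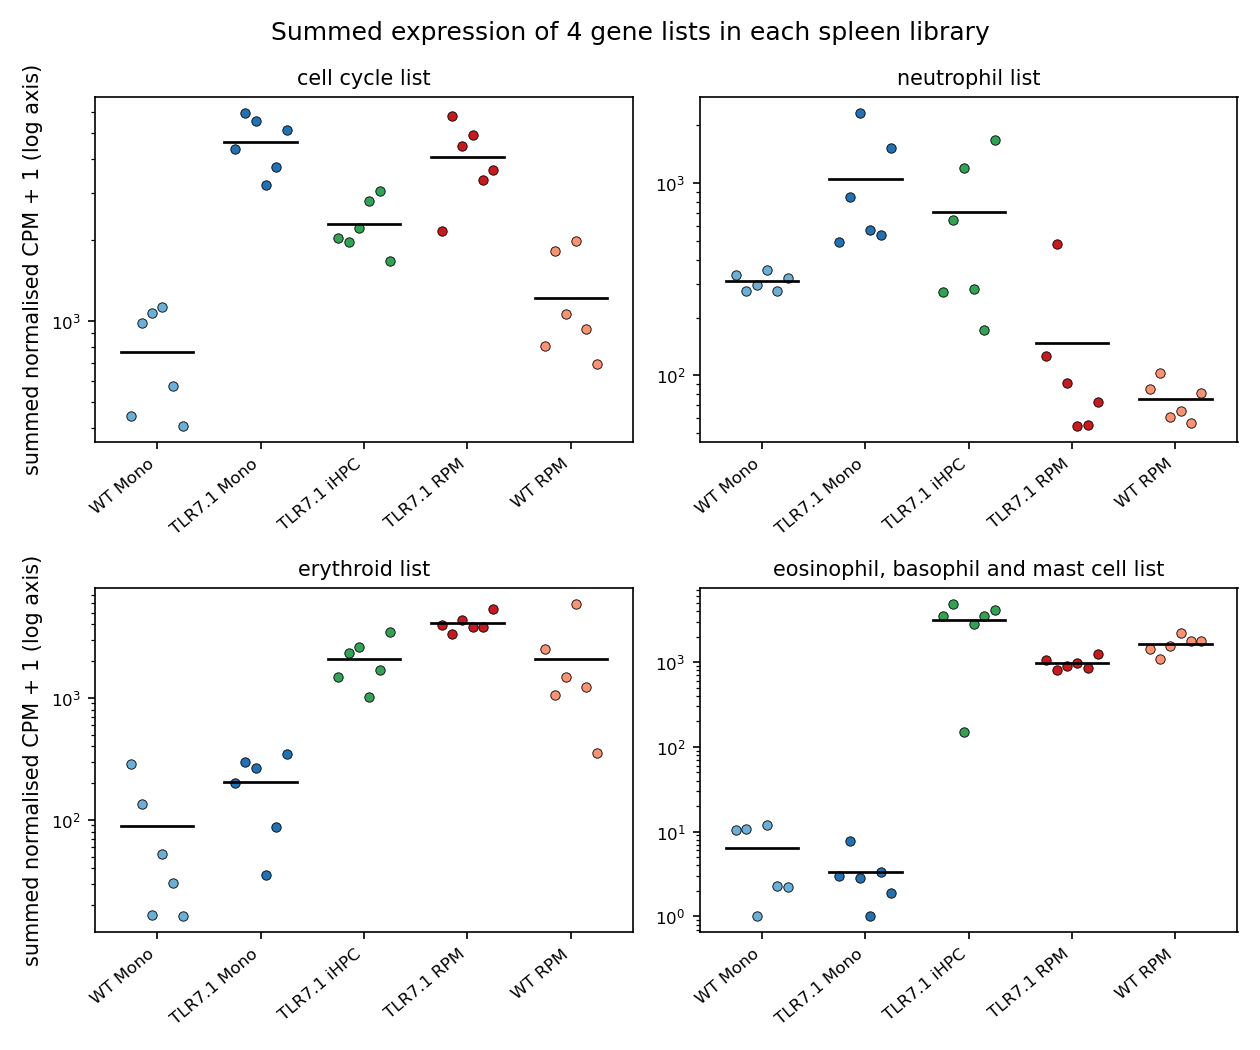
Sums of normalised CPM over the cell cycle, neutrophil, erythroid and eosinophil, basophil and mast cell lists in each of the 30 libraries, by group, with a bar at each group mean. The cell cycle sum averaged 4645 CPM in TLR7.1 Mono and 767 CPM in WT Mono, and the erythroid sum averaged 4090 CPM in TLR7.1 RPM and 2090 CPM in WT RPM.

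RPM of the genotypes were compared in the same way. Cell cycle and erythroid genes were higher in TLR7.1 RPM, while some genes of the inflammatory and dissociation response lists were lower and most red pulp macrophage markers were not called. Of 35 cell cycle genes, 22 rose and none fell (29 adjusted over the list alone). Mki67 rose from 53.7 ± 34.4 to 423 ± 137 CPM (log2 2.96 ± 0.354), and Cenpf (log2 3.19 ± 0.547), Ccne1 (log2 3.17 ± 0.815) and Ccnb2 (log2 2.89 ± 0.542) rose as well, the call of Ccne1 being lost without mouse 24304 (log2 2.68). Camera placed them above other genes (adjusted p = 2.43e-23, and adjusted p = 0.0682 with an estimated correlation). Of 19 erythroid markers, 12 rose and none fell (14 adjusted over the list alone). Blood group genes Rhag (114.5 ± 84.1 against 1.90 ± 2.28 CPM, log2 5.52 ± 0.885), Rhd (log2 4.92 ± 0.939) and Ermap (log2 4.58 ± 0.872) and the red cell spectrin gene Sptb (log2 3.56 ± 0.898) led them. The list ranked above other genes in camera (adjusted p = 7.06e-12, and adjusted p = 0.0501 with an estimated correlation). The WT library of mouse 24323, the shallowest, held the highest erythroid sum of all 12 RPM libraries, 5909 CPM, of which 5160 came from 4 globin genes. Without it the WT mean was 1326 ± 789 CPM (n = 5) and 10 erythroid markers rose. The 15 markers other than globin summed to 1651 to 3043 CPM in TLR7.1 RPM and 8.6 to 886 in WT RPM, that of mouse 24323 included. Plasma cell genes were higher in 2 of 9 cases and lower in 1, Jchain by a log2 of 2.88 ± 0.872 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00915, and adjusted p = 0.253 with an estimated correlation). B cell genes were higher in 2 of 17 cases and lower in none, Ighm by a log2 of 2.17 ± 0.563 and Igkc by 1.79 ± 0.536 (3 adjusted over the list alone; camera adjusted p = 0.00526, and adjusted p = 0.437 with an estimated correlation). Their sum was 3531 ± 1201 CPM in TLR7.1 and 1598 ± 908 in WT RPM. Ighm lost its call without mouse 24107 (log2 2.01), and Igkc without 24068, 24107, 24323, 24308, 24214, 24415, 24416 or 24304 (log2 1.57 to 1.86). Jchain kept its call only without mouse 24117 or 24380 (log2 2.64 to 2.96 where it was lost).

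In all, 910 genes differed between TLR7.1 and WT RPM, 494 higher and 416 lower, and 381 and 292 of these changed at least 2-fold. With scaling factors from genes of low read density, 598 were higher and 313 lower of 911, so the share of higher calls was 65.6% in place of 54.3%. Of 25 red pulp macrophage markers, 3 fell and none rose (5 and 1 adjusted over the list alone), Cd163 (log2 -1.71 ± 0.339), Itgad (log2 -0.73 ± 0.234) and Treml4 (log2 -0.67 ± 0.168). Itgad kept its call only without mouse 24068, 24117 or 24380 (log2 -0.73 to -0.57 where it was lost). Slc40a1 (1812 ± 425 against 2551 ± 540 CPM) and Spic (1209 ± 208 against 1517 ± 194 CPM) did not pass the test (adjusted p = 0.478 and 0.336), although limma-voom and thinned counts called Slc40a1 lower (log2 -0.50 and -0.67). The camera adjusted p of this list was 0.0142, and adjusted p = 0.43 with an estimated correlation. Iron genes went both ways, 3 higher and 2 lower of 23 (the same adjusted over the list alone; camera adjusted p = 0.697), with Tfrc (log2 2.44 ± 0.409) and Cp (log2 1.74 ± 0.417) higher and Cd163 lower. Type I interferon genes rose in 7 of 47 cases and fell in 1 (the same adjusted over the list alone). Isg20 (log2 2.22 ± 0.423), Oas3 (log2 1.87 ± 0.565) and Rsad2 (log2 1.68 ± 0.263) rose, and Ifi203 fell (log2 -0.84 ± 0.218). Oas3 lost its call without mouse 24117, 24107, 24308, 24214, 24415 or 24416 (log2 1.51 to 1.86), and Ifi203 without 24214 or 24416 (log2 -0.74 and -0.71). Without mouse 24107, 24308, 24214, 24415 or 24416, 4 interferon genes rose in each case, and the camera adjusted p of 0.0242 became adjusted p = 0.515 with an estimated correlation. Inflammatory genes fell in 7 of 28 cases and rose in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0776). The eosinophil chemokine gene Ccl24 fell from 369.5 ± 380.4 to 12.0 ± 12.5 CPM (log2 -4.67 ± 0.631), and Tnf fell (log2 -2.82 ± 0.886), while Sod2 rose (log2 0.63 ± 0.168). Tnf kept its call only without mouse 24028, 24068, 24323, 24214 or 24416 (log2 -3.06 to -1.58 where it was lost). Without mouse 24117, 24107, 24214, 24261, 24415 or 24304, 4 inflammatory genes fell in each case, and 3 fell without mouse 24308. Dissociation response genes fell in 6 of 19 cases (8 adjusted over the list alone), Dusp1 by a log2 of -1.16 ± 0.247 and Fos by -0.94 ± 0.223 (camera adjusted p = 1.42e-05, and adjusted p = 0.137 with an estimated correlation).

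The largest rises in TLR7.1 RPM were those of Ypel4, 82.6 times by pooled counts (22.6 to 687), Rhag, Slc43a1 (log2 5.13 ± 0.851), Smim5 (log2 4.65 ± 0.849), Smim1 (log2 4.23), Mylpf (log2 4.20), Pdzk1ip1 (log2 4.16), Ctse (log2 3.77), the blood group gene Kel (log2 3.70) and Pnp2 (log2 3.68). Rhag is one of the erythroid markers above. Whether RPM or erythroid cells in the sort held these transcripts was not tested. The largest falls were those of Apol7c, 268 times by pooled counts (47.6 to 10600), Ccl24, Spns3 (log2 -4.33), Tspan15 (log2 -4.00), Nos1 (log2 -3.34), Lncpint (log2 -3.29), Rsad1 (log2 -3.08), Ccdc126 (log2 -3.08), Epn2 (log2 -2.87) and Iqce (log2 -2.80). Rsad1 lost its call without mouse 24107, 24323, 24308, 24214 or 24304 (log2 -3.07 to -2.71), and Ccdc126 without mouse 24416 (log2 -2.04). Within collection dates, the median log2 fold change of the erythroid list was 1.43 on 13 December, 2.22 on 21 December with 1 WT library, and 3.82 on 26 December, and that of the cell cycle list 1.69, 1.18 and 2.28. For the type I interferon list these medians were 0.30, 0.86 and -0.05, so its direction did not hold on every date. Within 13 December edgeR called 0 genes and 1409 had an unadjusted p under 0.05, and within 26 December it called 198. Thinned counts gave 269 genes. The fit with only the 12 RPM libraries gave 160, fewer than that of Mono, so 910 does not rank RPM over Mono. Leaving out single mice gave 584 (without 24214) to 1354 (without 24117).

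Whether genotype acted differently in RPM and Mono was tested as the difference of the effects. In all, 76 genes passed, with the effect in RPM above that in Mono for 44 and below it for 32. The interferon-stimulated genes Rsad2 (log2 difference 2.21 ± 0.361) and Isg20 (2.54 ± 0.566) changed more upward in RPM, and they were the 2 genes called of the 47 in the type I interferon list. The complement genes C1qa (log2 difference -2.40 ± 0.425), C1qc (-1.99 ± 0.411) and Cfp (-0.96 ± 0.209) had an effect in RPM below that in Mono, 3 of 14 in that list (6 lower and 1 higher adjusted over the list alone). Isg20 lost its call without mouse 24323, 24308, 24214, 24261, 24415 or 24304 (log2 2.33 to 2.53), C1qc without 24323, 24415, 24416 or 24304 (log2 -1.86 to -1.66) and Cfp without 24107, 24323, 24261, 24415 or 24304 (log2 -0.94 to -0.83). C1qa was 1079 ± 264 CPM in TLR7.1 RPM and 1091 ± 257 in WT RPM. Camera gave the complement list an adjusted p = 0.000762, and adjusted p = 0.109 with an estimated correlation. The 10 genes with the largest differences included Smim5 (log2 difference 4.89 ± 0.99), Ctse (4.19 ± 0.678), Dyrk3 (3.96 ± 0.958), Rgcc (3.29 ± 0.805) and Ccdc126 (-3.68 ± 0.914). Ckap4, Apol7c, Mras, Adora2b and Depdc7 were the others, each with 0 to 2 counts in 1 of the 4 groups, so their fitted size depends on the prior count. Of the 10, Smim5, Ctse, Apol7c and Mras kept their calls whichever mouse was left out. Smim5 and Ctse were also among the largest rises in TLR7.1 RPM, whose source, RPM or erythroid cells in the sort, was not tested. Dyrk3 was called only without mouse 24028, 24068 or 24117 (log2 3.64 to 4.03 where it was lost) and Rgcc only without 24068 or 24117 (2.91 to 3.42). Ccdc126 was called only without 24117 or 24214 (-3.85 to -3.46 where it was lost, and -2.54 without 24416). Ckap4 lost its call without mouse 24117, 24107, 24214, 24261, 24415 or 24416 (4.26 to 5.03). Adora2b lost it without any mouse but 24214 (-5.70 to -5.36, and -3.57 without 24117), and Depdc7 without any but 24028, 24068, 24214 or 24416 (-4.77 to -3.86, and -2.98 without 24117). Of 35 cell cycle genes 1 was called, Kif11 (log2 difference -3.19 ± 0.722; lost without mouse 24117, 24308, 24261 or 24415, log2 -3.11 to -2.95), and of 19 erythroid markers edgeR, DESeq2 and limma-voom called 0, with 3 at an unadjusted p under 0.05. Of 11 neutrophil markers edgeR called 0, DESeq2 1 and limma-voom 3, with 1 at an unadjusted p under 0.05 in edgeR. Within 13 December edgeR called 0 genes and 663 had an unadjusted p under 0.05, and within 26 December it called 4. DESeq2 called 209 genes, limma-voom 126, thinned counts gave 15, and leaving out single mice gave 29 without mouse 24415 and 145 without mouse 24117.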

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

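The tests of Prg2, of the genes lacking with mouse 24261, of that library's depth and of its other iHPC genes, the division of the erythroid list into globin and other genes, the exchanges of single RPM libraries, the test of free RNA, and both tests of scaling or depth were chosen only after the result was seen. The correlations, the within-date values, the splits and the search for libraries far from their group were chosen before.

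Mcpt8, Prss34, Cpa3, Fcer1a, Ms4a2 and Gata2, of the basophil and mast cell list, summed to 2485 to 4516 CPM in 5 iHPC libraries. They held 0.9 CPM with mouse 24261, where Cd200r3 of that list held 129 (others 151 to 334). Lower depth of that library is argued against, since it would hold 3351 counts of the 6 genes at the mean share of the other 5 and held 1. Expression together with the other genes that mark iHPC was examined with 374 genes higher in iHPC than in both other populations. Their median log2 ratio in that library to the others was -0.005 (quartiles -0.246 and 0.147). They were called with that library among the 6, which favours genes it holds, so the ratio cannot decide this. Basophils are argued against as the source of Prg2, which reached 686 CPM with mouse 24308 alone (SD 4.3 for its log2 ratio to the other basophil genes over 5 libraries). Basophils sorted with the iHPC cannot be told apart from expression of this group of genes within some iHPC. Of 7 list genes at 20 CPM, 6 were among the 19 genes under 10% of the others (0.0226 expected by chance). The other 13 are not in the list, which does not show whether basophils hold them. The gate removed Siglec-F-positive cells but used no basophil marker, so it does not exclude basophils.

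Erythroid transcripts were higher in TLR7.1 than in WT RPM, with 12 of 19 genes called and sums of 4090 ± 698 and 2090 ± 2000 CPM, although the WT library of mouse 24323 held more (5909) than any TLR7.1 RPM library, 5160 of it globin (15 other genes: 8.6 to 886 in WT, 1651 to 3043 in TLR7.1). Free RNA of the spleen suspension, alike in every population, is argued against, because the list was higher in RPM than in Mono of the same 6 TLR7.1 spleens by a median log2 of 6.30, also with the gene at 0 in Mono set to its bound. Scaling or depth is argued against too, since at least 91.7% of the called genes still tested stayed called in each of 5 scaling and depth settings, although thinning left 2 of the 12 in the test. Erythroid cells, ingested or attached, cannot be told apart from expression by the RPM themselves, since cells were sorted as CD45.2-positive and the correlation of erythroid and cell cycle sums over the 6 TLR7.1 RPM libraries decided nothing (Spearman -0.543, exact permutation p = 0.297, adjusted p = 0.297; Pearson -0.321, exact p = 0.558, adjusted p = 0.558, and 0.188 without mice 24380 and 24107; 2 relations computed). The TLR7.1 genotype remains open as a biological cause and was not tested apart from these.

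Cell cycle transcripts were higher in TLR7.1 than in WT Mono, with 25 of 35 genes called. Scaling or depth is argued against, since at least 87.5% of the called genes still tested stayed called in each of 5 settings, the lowest in thinned counts with 14 of 16. Collection date or age is argued against by within-date median log2 folds of 2.96, 1.79 and 3.12, the smallest from 1 WT library on 21 December, against 2.72 over all dates. Dividing neutrophil precursors in the Mono sort cannot be told apart from division of the monocytes, since Ly6G-positive cells were removed and the neutrophil and cell cycle sums over the 6 TLR7.1 Mono libraries gave Spearman 0.6 (exact permutation p = 0.242, adjusted p = 0.297) and Pearson 0.616 (exact p = 0.204, adjusted p = 0.408), and 0.817 without mice 24261 and 24380. A change of dividing monocytes with the TLR7.1 genotype stays open and was not tested apart from it.

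Counting the real one, a share under 0.05 of the splits gave as many genes in each comparison, without correction over the comparisons. This argues against chance as the origin of the counts between populations and between genotypes in Mono, where no other split reached them. In RPM between genotypes, for the interaction and for genes apart from both populations, other splits gave more genes, so chance is not excluded. Among the 32 splits that part the libraries of all 6 mice, only 1, the real one, gave as many genes between iHPC and RPM (2993, highest other 985), iHPC and Mono (4270 and 513), TLR7.1 RPM and Mono (5135 and 2070) and WT RPM and Mono (5098 and 2353). The other 68 splits, which leave some mice with both libraries on one side, reached at most 1319, 622, 919 and 1628. Between genotypes in Mono, 1 of 100 splits gave as many genes (232, highest other 3). In RPM, 3 of 100 did (910, highest other 1507), and for the interaction 2 of 100 (76, highest other 109). The splits with more genes exchanged the WT mouse 24117, whose RPM library is the deepest of its group, with TLR7.1 mouse 24380 (1507 genes in RPM) or 24068 (1442 in RPM, 109 for the interaction). Its RPM library did not raise the count in most cases: exchanged with mice 24107, 24308, 24261 and 24304 it gave 5, 373, 438 and 844 genes. Exchanges of the other 5 WT libraries gave 6 to 584. What sets these libraries apart was not tested. Without mouse 24117, 1354 genes were called in RPM and 145 for the interaction. For genes apart from both populations, 3 of 100 rearrangements gave as many (673, highest other 2915). The highest put the Mono libraries in the place of iHPC, so that it measures how far Mono differ from RPM and iHPC, and another with 971 genes kept iHPC in place and mixed Mono with RPM.

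Of 126 sets of 6 libraries, 17 (13.5%) held a library whose distance from the nearest other exceeded Dixon's limit, where chance gives about 1 in 20. In WT RPM, mouse 24117 stood apart with a total of 1511480 counts (others 95002 to 597638), plasma cell markers at 1553.5 CPM (73.7 to 347.1), endothelial and stromal markers at 70.1 CPM (21.4 to 37.3) and Ly6c2 at 30.9 CPM (0 to 10.7). Mouse 24323 held Ccr2 at 53.5 CPM in that group (0 to 9.0). The TLR7.1 Mono library of mouse 24380 had a total of 1157446 counts (others 1522303 to 1719010) and dissociation response genes at 7200.2 CPM (5285.7 to 5786.4). Eosinophil, basophil and mast cell markers in that group were at 6.8 CPM with mouse 24107 (0 to 2.3). In TLR7.1 RPM, mouse 24107 had T and NK cell markers at 2376.5 CPM (74.2 to 553.4) and neutrophil markers at 480.6 CPM (53.6 to 125). Mouse 24308 held Itgam at 46.6 CPM there (0 to 17.2). The iHPC library of mouse 24380 stood apart with 10916 genes detected (others 13037 to 13814), plasma cell markers at 197.2 CPM (292.4 to 342.2), Adgre1 at 535.3 CPM (375.2 to 433.98) and a correlation with Mono of the same mouse, across genes, of 0.574 (0.69 to 0.723). T and NK cell markers in iHPC were at 723.1 CPM with mouse 24107 (13.9 to 147.9), and plasmacytoid dendritic cell markers at 775 CPM with mouse 24304 (855.8 to 904.1).

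The genotype effect differed between RPM and Mono in 76 genes by the interaction test. Among the genes with the largest log2 differences, Ckap4 (4.98), Smim5 (4.89), Ctse (4.19), Dyrk3 (3.96) and Rgcc (3.29) changed more upward in RPM. For Apol7c (-9.85), Mras (-6.01), Adora2b (-5.47), Depdc7 (-4.24) and Ccdc126 (-3.68) the effect in RPM was below that in Mono. Each had a lower mean CPM in TLR7.1 than in WT RPM. Each but Depdc7 had a higher one in TLR7.1 than in WT Mono, and Depdc7 a lower one (46.3 against 54.13 CPM).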

How the results depend on the processing

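The settings chosen only after the data were seen were those without the 3 libraries under 300000 counts, with scaling from genes of low read density, with counts corrected for saturation, without dense genes, and with mouse 24261 as the only iHPC library. In every setting each count of genes stayed within 1.5 times its value in the report unless it is given here. Counts thinned to the smallest library, which leave 4470 of 11030 genes to test, gave 1145 genes between iHPC and RPM, 1809 between iHPC and Mono, 2157 and 2265 between RPM and Mono in TLR7.1 and WT mice, 50 between genotypes in Mono, 269 in RPM, 15 for the interaction and 263 apart from both populations. With mouse 24261 as the only iHPC library, whose spread is assumed to be that of the other groups, the counts were 645 against RPM, 1173 against Mono and 62 apart from both. Of the called and testable genes, 1462 of 1498 higher and 1493 of 1494 lower than RPM kept their direction there, 2076 of 2128 and 2141 of 2141 against Mono, and 371 of 375 and 297 of 297 apart from both. Ier3 was reversed against RPM in that setting (log2 -0.29, SE 0.844, adjusted p = 0.933). Fits of only the groups compared gave 1753 genes between iHPC and RPM, and between genotypes 160 in RPM and 737 in Mono. At an adjusted p under 0.01, 1950 genes differed between iHPC and RPM, 140 and 322 between genotypes in Mono and RPM, 25 for the interaction and 430 apart from both. Within 13 December, with 2 mice per genotype, edgeR called 0 genes in Mono, 0 in RPM and 0 for the interaction, with 329, 1409 and 663 at an unadjusted p under 0.05, and within 26 December it called 105, 198 and 4. DESeq2 called 209 genes for the interaction, and limma-voom called 126 there and 405 between genotypes in Mono. With the replicate block, the mouse as a random effect in limma-voom, these limma-voom counts became 164 and 400, and 880 between genotypes in RPM became 884. The mouse as a fixed term in edgeR gave 2590 and 3912 genes for iHPC against RPM and Mono, 4702 and 4316 for RPM against Mono in TLR7.1 and WT mice and 589 apart from both, so that the block moved no other count past 1.5 times. Leaving out single mice gave 160 to 263 genes between genotypes in Mono, 584 (without 24214) to 1354 (without 24117) in RPM, and 29 (without 24415) to 145 (without 24117) for the interaction, with 46 without 24308 and 44 without 24261 or 24416. The position over RPM-high genes was 0.483 with an 8-fold limit and 0.477 with a pseudocount of 5 CPM, and over Mono-high genes it was 0.693 with that pseudocount, past the midpoint at an exact p of 0.031, the smallest possible. The difference of the correlations, -0.00683 in the report, was 0.006 with that pseudocount, 0.001 with Spearman's coefficient, and -0.021 to 0.009 without single mice, so its sign is undecided. Of 9952 values under alternatives of genes that the naming rule or the text takes, 9391 kept direction and call, 526 lost the call, 10 gained it, 1 reversed and 24 moved without a call. Where the setting itself does not show it, the cause was not tested. Depth limits the RPM groups most, since totals there start at 95002 and 268275 counts, so a gene not called in RPM may still differ.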

Other observations

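The gene lists described here were fixed in advance, and of their tests, those with mouse 24261 as the only iHPC library were chosen only after the result was seen. Beyond the groups in the report, iHPC differed from RPM in lysosomal, lipid and transcription factor genes. Of 38 lysosome genes, 14 were lower and 3 higher in iHPC (the same adjusted over the list alone), with the transcription factor gene Mitf (log2 -2.08 ± 0.454), the phospholipase gene Pla2g15 (log2 -1.84 ± 0.24) and the cathepsin D gene Ctsd (log2 -1.81 ± 0.176) lower and Ctsa higher (log2 0.60 ± 0.165; not called without mouse 24304, log2 0.48). Camera gave the lysosome list an adjusted p = 0.000675, and adjusted p = 0.274 with an estimated correlation. Of 18 cholesterol efflux genes and targets of the LXR receptors, 6 were lower and 3 higher (7 and 3 adjusted over the list alone). The lipoprotein genes Apoc1 (log2 -7.30 ± 0.527) and Apoe (log2 -2.49 ± 0.29) and the cholesterol transporter gene Abca1 (log2 -3.43 ± 0.478) fell, and the phospholipid transfer protein gene Pltp rose (log2 2.46 ± 0.483). The camera adjusted p of that list was 0.00723, and adjusted p = 0.0996 with an estimated correlation. Myeloid transcription factors went both ways, 16 higher and 10 lower of 42 (18 and 11 adjusted over the list alone), with a median log2 fold change of 0.42, a mean of -0.03 and a camera adjusted p of 0.192. Runx2 (log2 5.0 ± 0.674) and Nr4a1, which is required by Ly6C-low monocytes (log2 2.55 ± 0.326), rose, and Tfec fell (log2 -7.17 ± 0.781). Genes of Toll-like receptors and their signalling were higher in 10 of 29 cases and lower in 4 (10 and 5 adjusted over the list alone; camera adjusted p = 0.126), Irak3 by a log2 of 1.92 ± 0.213 and Cd180 by 1.75 ± 0.284, with Tirap lower (log2 -1.40 ± 0.467; not called without mouse 24068, 24308 or 24380, log2 -1.32 to -1.16). With mouse 24261 as the only iHPC library, 4 lysosome and 5 LXR genes were called lower and 8 transcription factor and 2 Toll-like receptor genes higher, and Mitf (log2 -2.58), Cd180 (1.39) and Tirap (-1.64) lost their calls.

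Against Mono of the same spleens, some cholesterol synthesis, glycolysis and cell cycle genes were lower in iHPC, although most members of each list did not pass as lower. Of 17 cholesterol synthesis genes, 7 fell and none rose (7 adjusted over the list alone), Fdft1 by a log2 of -2.99 ± 0.496 and Mvd by -2.64 ± 0.448 (camera adjusted p = 0.0103, and adjusted p = 0.118 with an estimated correlation). Of 21 glycolysis genes, 9 fell and 2 rose (the same adjusted over the list alone). The lactate transporter gene Slc16a3 (log2 -3.58 ± 0.61) and the phosphofructokinase gene Pfkp (log2 -1.75 ± 0.321) fell, and Pdk1, whose product holds pyruvate back from the mitochondria, rose (log2 2.04 ± 0.394). The glycolysis list had a camera adjusted p of 0.0345, and adjusted p = 0.398 with an estimated correlation. Of 35 cell cycle genes, 15 fell and 3 rose (18 and 3 adjusted over the list alone), the mitotic genes Cdc20 by a log2 of -3.04 ± 0.686 and Aurkb by -2.77 ± 0.493 among the former and the cyclin gene Ccnd1 among the latter (log2 3.68 ± 0.562). For this list camera gave an adjusted p = 0.0434, and adjusted p = 0.724 with an estimated correlation. Toll-like receptor and signalling genes went both ways, 9 higher and 11 lower of 29 (the same adjusted over the list alone; camera adjusted p = 0.242). Irf7 (log2 -2.19 ± 0.234) and Cd14 (log2 -2.12 ± 0.198) fell and Cd180 rose (log2 1.56 ± 0.274). All 7 mitochondrially encoded genes tested were higher (7 adjusted over the list alone), mt-Nd6 by a log2 of 1.37 ± 0.294 and mt-Nd2 by 1.32 ± 0.223 (camera adjusted p = 0.0088, and adjusted p = 0.47 with an estimated correlation). Xist, named although it stands outside the rule for named genes, was 444 ± 76.6 CPM in iHPC and 133 ± 20.2 CPM in Mono of these female mice (log2 1.74 ± 0.207). With mouse 24261 as the only iHPC library, 1 cholesterol synthesis, 2 glycolysis and 5 Toll-like receptor genes were called lower and 1 mitochondrial gene higher, and Mvd (log2 -1.72), Pfkp (-1.88), Pdk1 (1.04), Cdc20 (-3.59), Aurkb (-3.21), Cd180 (1.16) and mt-Nd6 (1.04) lost their calls.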
